A study of Homo sapiens with 24 samples.

How the data were processed

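RNA immunoprecipitation followed by sequencing was measured in BE2C cells with LIN28B knocked out and a FLAG-tagged form re-expressed: wild-type, a mutant of the cold-shock domain, a mutant of the zinc knuckle domain, or the double mutant. Each form had 3 input and 3 precipitate libraries, 24 in all, of polyA-selected RNA. The labels number the libraries 1 to 3 but do not say what a number stands for, so the 3 may be technical replicates. Knockout and untransfected cells named in the series design have no library in the tables used here.

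Per the labels the authors used kallisto 0.44.0 and DESeq2 1.24.0 on hg38, with no role or order given for either. The values of the 3 count tables are a signal, normalized counts per gene deposited by the authors, 1 table per form with its 12 libraries normalized together. The factors that link one table to another differed by gene and by library, so whole reads could not be recovered. Which term of the authors' normalization causes this is not given, and it was not tested. Planned count tests with edgeR and DESeq2 and a planned test of the wild-type form against each single mutant were therefore not run, and values from different tables are only set side by side. The authors' table of comparisons holds log2 fold changes with their SE on the log2 scale, a test statistic that is a score, and a p-value with its adjusted form, for 15499 genes. The authors' annotation release, the way transcripts were summed to genes and any filter are not given in the sources used here, nor is the raw depth.

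Raw depth could therefore not be described, since sums of normalized values per library, 10374235 to 17301929, do not measure it. In each table these sums were lowest in inputs, higher in double-mutant precipitates and highest in precipitates of the other form. Libraries were compared by the spread between replicates. Correlations of log2 values between libraries of a group were 0.978 to 0.986 over the tested genes, and no 2 libraries were identical. Differences were estimated on log2 of the value plus 1, which understates changes of genes with low values.

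Each table was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend) on log2 of the value plus a pseudocount of 1, for genes with a mean of at least 10 over the 12 libraries: 14757 of 28012 genes in the wild-type table, 14474 of 27486 in the CSD table and 14713 of 27924 in the ZKD table. The model had 4 group means and 8 residual degrees of freedom. The main contrast was IP minus input of the form, less IP minus input of the double mutant, and the others were IP against input in each form and input against input. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The double mutant's IP against input was taken from the wild-type table. With 3 against 3 libraries there are only 10 splits of the samples, so a permutation of labels cannot give a share under 0.1 and limma p-values are reported.

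A total of 18 gene lists were written down before the data were examined, as were the groups, the comparisons, the tests and the alternatives named here except where said otherwise. The lists held cytosolic large and small ribosomal subunit proteins, mitochondrial ribosomal proteins, translation initiation factors, elongation and termination factors, aminoacyl-tRNA synthetases, ribosome biogenesis factors, the S6 kinase and mTOR pathway, adrenergic neuroblastoma transcription factors, mesenchymal markers, neuronal genes, let-7 targets, RNA-binding and splicing factors, cell cycle genes, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded transcripts, secretory pathway genes and replication-dependent histones. They were tested with camera at a preset correlation of 0.01, with a correlation estimated from the residuals, and with fry, and adjusted over the 18 lists of a comparison. Members were also counted after adjustment over the list alone.

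Genes were named by a fixed rule: per enrichment the 10 largest and 10 smallest differences among genes that passed, had a mean of at least 50 and had all 3 IP/input ratios of the form beyond all 3 of the double mutant, taking libraries of the same number. Such separation of 3 from 3 arises by chance in 10% of genes. LIN28B, RPS6KB1, RPL24 and MYCN were always given, as were the 2 highest and 2 lowest members of a list where they help to describe it. For IP against input and for inputs the 5 largest differences each way with no overlap of libraries were used, and genes whose call ended without 1 library are kept for the part on sensitivity. Some genes of this set are not reported here.

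Positions, gene types, lengths and sequences came from GENCODE 29 on GRCh38, the assembly that hg38 also names, and 27897 of 29299 gene symbols (95.2%) were matched, 15499 by the deposited ID and 12398 by symbol. Length, GC content and tetramers were taken from one transcript per gene (an APPRIS principal one, then one of the basic set, then the longest). Lists matched for length, or for length, GC content and abundance, were drawn 10000 times from the 100 nearest protein-coding genes of each member. After the data were seen, a quadratic fit on the 3 properties was added to move matched genes to the properties of each member. Processed pseudogenes of a gene were counted by their annotated names. The correlation expected from shared double-mutant libraries alone came from 20 simulations.

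The procedure was tested on simulated counts drawn around the real gene means with the real spread, with known differences added to some genes. At log2 1, 75.4% of the added differences passed in the wild-type table, 67.7% in the CSD table and 51.5% in the ZKD table, at log2 0.5 the shares were 26.2%, 20.9% and 23.9%, and at log2 2 they were 80.3%, 78.8% and 86.2%. Of all calls 5.56%, 5.98% and 8.62% fell on unchanged genes. In the real comparisons 60.3 to 63.5% of the tested genes passed. With so few changed genes the adjustment was stricter in the simulation, so these shares do not carry over to the real comparisons.

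Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, scaling of each library to an equal total, cyclic loess scaling, limma without the trend and with robust moderation, limma treat at log2 0.5, precipitates alone, the 6 libraries of a contrast alone, a replicate block, and each library left out in turn. Leaving out double-mutant libraries for the correlations between forms and equal totals for the gene lists were added after the data were seen. Whether numbers pair libraries was checked by correlating residuals of libraries with the same number, which gave -0.0643 to 0.0923, so the number was not used in the main model. Further values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.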

Results

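The series measured which RNAs came down with LIN28B in BE2C cells, a MYCN-amplified neuroblastoma line. LIN28B, an RNA-binding protein that blocks let-7 maturation and also binds mRNAs, had been knocked out, and a FLAG-tagged form had been put back. The 4 forms were wild-type LIN28B, a mutant of the cold-shock domain (CSD mutant), a mutant of the zinc knuckle domain (ZKD mutant), and a double mutant with both RNA-binding domains changed. Each form had 3 input and 3 FLAG precipitate libraries, so 24 polyA-selected, paired-end libraries made 8 groups of n = 3. The data came as 3 tables, each with 12 libraries of one form and the double mutant, normalized one table at a time. Summed normalized values per library ranged from 11190121 to 16805013 in the wild-type table, from 10374235 to 15831606 in the CSD table and from 10964133 to 17301929 in the ZKD table. The number of raw reads is not given in the sources used here.

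For each form the main question was which RNAs were more or less abundant in the precipitate, relative to input, than with the double mutant, which served as the background. This difference, log2 IP/input of the form minus log2 IP/input of the double mutant, is called enrichment below. The next question was how precipitate and input differed within each form, and another was how the inputs differed, since a change of the cells' RNA can look like a change of binding. Values after ± are the SE of the limma fit for log2 differences and the SD between libraries (n = 3) for normalized values. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

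The re-expressed gene itself differed between forms. LIN28B (ENSG00000187772, protein-coding, chromosome 6, 104936616 to 105083332, plus strand of GRCh38) stood at 6830.4 ± 151 in wild-type inputs and 3984 ± 77.3 in double-mutant inputs of the wild-type table, at 5508 ± 55.0 and 3619 ± 72.2 in the CSD table, and at 4306 ± 229 and 3849.7 ± 75.0 in the ZKD table (n = 3 each). Against the double mutant, input LIN28B rose with the wild-type form (log2 0.78 ± 0.06, adjusted p = 5.1e-07) and the CSD mutant (0.61 ± 0.05, adjusted p = 1.1e-05), and the ZKD difference of 0.16 ± 0.06 did not pass (adjusted p = 0.061). In the precipitates LIN28B RNA reached 12765 ± 651 with the wild-type form, 6029.6 ± 181 with the CSD mutant and 3964 ± 118 with the ZKD mutant, against 5247 ± 343, 4733 ± 299 and 5093 ± 332 with the double mutant of the same tables. Its enrichment rose with the wild-type form (0.51 ± 0.08, adjusted p = 6.0e-05) and fell with the CSD mutant (-0.26 ± 0.07, adjusted p = 0.0039) and the ZKD mutant (-0.52 ± 0.08, adjusted p = 3.6e-05), and the wild-type value shrank to 0.09 (adjusted p = 0.31) after cyclic loess scaling. In precipitates alone, with no regard to input, the CSD-mutant value turned to 0.35 (adjusted p = 0.00023), and scaling to equal totals turned that precipitate difference to -0.026 (adjusted p = 0.65). The tables do not separate RNA of the re-expressed form from RNA of the knocked-out locus.

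The composition of the precipitates differed between forms. Cytosolic ribosomal protein mRNAs made up 11.05 ± 0.737% of the wild-type, 14.1 ± 0.530% of the CSD-mutant and 8.89 ± 0.220% of the ZKD-mutant precipitates, against 3.66 ± 0.0689% of the double-mutant precipitates and 5.06 to 5.09% of the inputs (means of n = 3). Transcripts of the 13 protein-coding mitochondrial genes took 12.8 ± 0.660% of wild-type inputs and 4.64 ± 0.203% of wild-type precipitates, and 12.2 ± 0.224% and 3.45 ± 0.295% with the CSD mutant. With the ZKD mutant they took 12.6 ± 0.673% of inputs and 13.8 ± 0.0784% of precipitates, and with the double mutant 10.5 ± 0.00583% and 9.89 ± 0.697%. Counts of these transcripts below are counts of genes. MT-ATP8 (8366 to 8572) and MT-ATP6 (8527 to 9207) overlap on the same strand, so they are not independent.

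**Figure D1:**
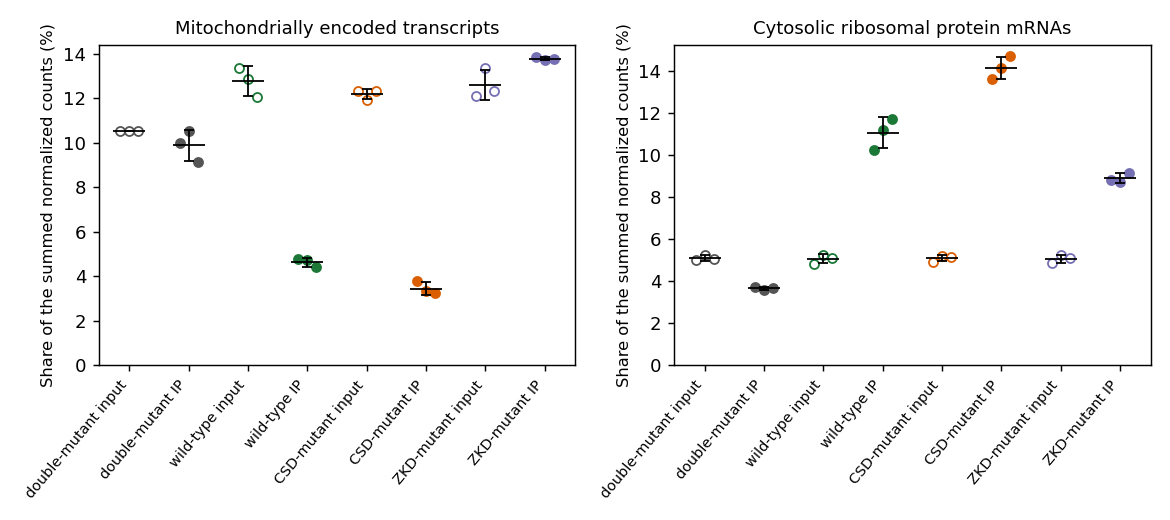
Share of the summed normalized values taken by the 13 protein-coding mitochondrial genes (left) and by cytosolic ribosomal protein mRNAs (right) in each library. Points are libraries, bars are mean and SD (n = 3 per group), and double-mutant libraries are shown from the wild-type table.

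With wild-type LIN28B, PET100 (ENSG00000229833, protein-coding, chromosome 19, 7629737 to 7631956, plus strand), an assembly factor of cytochrome c oxidase, rose by 4.09 ± 0.14 in the precipitate. It went from 457 ± 27.7 in input to 3863 ± 367 in the wild-type precipitate, and from 469.6 ± 41.8 to 232 ± 22.5 with the double mutant (n = 3 each). The complex III subunit UQCRB (3.87 ± 0.12), the outer-membrane translocase subunit TOMM7 (3.85 ± 0.14), the complex I subunit NDUFB3 (3.82 ± 0.14), IFI27L2 (3.77 ± 0.23) and ZSWIM7 (3.60 ± 0.16) also rose. RPL36A (3.71 ± 0.11) and RPS27A (3.64 ± 0.13), which encodes ubiquitin fused to a small-subunit protein, rose as well, and RPS27A reached 46670 ± 7606 in the precipitate from 4155 ± 246 in input. SNURF rose by 3.61 ± 0.62, a value that is uncertain because its transcript also holds SNRPN.

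At the other end PRR36 (ENSG00000183248, protein-coding, chromosome 19, 7868719 to 7874379, minus strand) fell by 4.19 ± 0.19, with 37.8 ± 2.62 in the wild-type and 799 ± 86.7 in the double-mutant precipitate. The neuronal transcriptional repressor SCRT2 (-3.10 ± 0.25), the protease PRSS53 (-3.19 ± 0.47) and RIPOR1 (-3.12 ± 0.16) fell, as did the non-coding genes AC136944.2 (-3.78), AC026362.1 (-3.63) and AC084018.2 (-3.24) and the unclassified AC012676.5 (-3.36). The values of the pseudogene USP32P2 (-3.27) and of the readthrough gene ANKHD1-EIF4EBP3 (-3.08) are uncertain, since reads can belong to their parent genes. MYCN, the amplified oncogene of this line, fell by 0.74 ± 0.07 (adjusted p = 1.3e-07) and stood at 25880 ± 882 in the wild-type precipitate against 44374 ± 471 in that of the double mutant. RPL24 rose by 0.81 ± 0.13 (adjusted p = 5.2e-05), and the S6 kinase gene RPS6KB1 had -0.09 ± 0.16 (adjusted p = 0.65). Only after scaling to equal totals did RPS6KB1 pass, at -0.39 (adjusted p = 0.043).

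Lists given here with an estimated correlation passed camera at its preset correlation and not at the estimated one. Of the mRNAs for cytosolic ribosomal proteins, 41 of 46 of the large subunit rose and 0 fell (median 1.53, adjusted p = 0.207 with an estimated correlation), with RPL36A and RPL30 (3.07) highest. For the small subunit 31 of 32 rose and RPS26 (-0.61) fell (median 1.83, adjusted p = 0.199 with an estimated correlation), and RPS19 rose by 3.15. Many ribosomal protein genes have processed pseudogenes, which leaves single values uncertain. Of 77 mitochondrial ribosomal protein mRNAs 70 rose and 3 fell (median 1.29, adjusted p = 0.192 with an estimated correlation), from MRPL41 (3.49) and MRPL42 (3.46) to MRPL10 (-0.60) and MRPS2 (-0.48). Nuclear-encoded oxidative phosphorylation mRNAs gave 68 rises and 0 falls among 75 (median 1.80, adjusted p = 0.192 with an estimated correlation).

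Translation factors split by gene. Of 43 initiation factors 31 rose and 5 fell (median 0.87, adjusted p = 0.192 with an estimated correlation), with EIF3H (2.19) and the helicase EIF4A1 (1.99) at the top and the scaffold EIF4G3 (-1.70) and EIF5B (-1.39) at the bottom. Of 15 elongation and termination factors 11 rose and 2 fell (median 0.49, adjusted p = 0.192 with an estimated correlation), including EEF1G (2.57) and EEF1D (1.79) upward and the kinase EEF2K (-0.90) downward. Of 22 aminoacyl-tRNA synthetase genes 14 rose and 5 fell (median 0.41, adjusted p = 0.419 with an estimated correlation), with the complex members AIMP1 (1.97) and AIMP2 (1.38) highest. Of 72 ribosome biogenesis factors 42 rose and 13 fell (median 0.49, adjusted p = 0.207 with an estimated correlation), between NPM1 (2.12) and UTP20 (-1.83).

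Secretory pathway genes gave 30 rises and 7 falls of 51 (median 0.55, adjusted p = 0.192 with an estimated correlation), with the signal peptidase subunits SEC11A (3.12) and SEC11C (3.11) highest and SEC24A (-1.19) and SEC61B (-1.17) lowest. RNA-binding and splicing factors gave 29 rises and 13 falls of 50 (median 0.50, adjusted p = 0.221 with an estimated correlation), including HNRNPA1 (2.40) and SRSF11 (-1.06). Adrenergic neuroblastoma transcription factors gave 5 rises and 10 falls of 19 (median -0.72, mean -0.25, adjusted p = 0.192 with an estimated correlation), among them GATA3 (-1.45) and HAND2 (-1.42) against LMO1 (2.12). Of the 13 mitochondrially encoded genes 10 fell (median -1.08, adjusted p = 0.287 with an estimated correlation), most MT-ND5 (-2.67) and MT-ND6 (-2.51). MT-CO3 rose by 0.90 and turned to -0.11 under cyclic loess scaling. The value of MT-ND6 is uncertain, since it lies directly beside MT-ND5 on the other strand and strand use is not stated.

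The remaining lists did not pass as groups with the wild-type form. Cell cycle genes had 23 rises and 12 falls of 46 (median 0.31, adjusted p = 0.0505), from CKS2 (2.68) to the proliferation marker MKI67 (-2.39). S6 kinase and mTOR pathway genes had 8 and 12 of 28 (median -0.10, adjusted p = 0.308), with the GTPase RHEB (2.65) opposite RPTOR (-1.62) and MTOR (-1.31). Neuronal genes had 14 and 21 of 54 (median -0.14, adjusted p = 0.0968), with STMN2 (1.54) opposite ROBO1 (-1.82). The let-7 targets had 12 and 10 of 37 (median -0.15, adjusted p = 0.691), with DUSP12 (2.08) opposite IRS2 (-1.85), and equal totals turned the balance to 10 rises and 19 falls. Replication-dependent histones had 5 and 0 of 11 tested, out of 44 listed (median 0.95, adjusted p = 0.161). Mesenchymal markers had 4 and 1 of 15 (adjusted p = 0.684; 3 and 4 under equal totals), and their median of -0.10, mean of 0.26 and cyclic loess median of 0.20 differed in sign. Adjusted over the list alone, counts differed for the large subunit (42 rose), mitochondrial ribosomal proteins (72), ribosome biogenesis (43), neuronal genes (15), RNA-binding factors (14 fell), oxidative phosphorylation (1 fell) and the secretory pathway (31 rose and 8 fell).

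By limma 8897 of 14757 tested genes passed with the wild-type form, 4579 higher and 4318 lower, and 2588 and 2250 of these differed at least 2-fold. Scaling to equal totals moved the median of all genes from -0.03 to -0.33 and the split to 3439 higher and 5856 lower. By camera with a preset correlation 12 of the 18 lists passed, and with an estimated correlation 0 passed (3 at an unadjusted p under 0.05).

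With the CSD mutant, RPL35 (ENSG00000136942, protein-coding, chromosome 9, 124857880 to 124861981, minus strand), a large-subunit protein, had an enrichment of 4.16 ± 0.07. It went from 4594 ± 126 in input to 52612 ± 1396 in the CSD-mutant precipitate (n = 3 each). The enrichment also takes off IP/input of the double mutant, so it is not the log2 ratio of these values. RPS27A (4.34 ± 0.07), RPL31 (4.11 ± 0.07), the mitochondrial ribosomal MRPL41 (4.06 ± 0.11), PET100 (4.41 ± 0.13), IFI27L2 (4.75 ± 0.22) and STUM (4.82 ± 0.60) rose too. The STUM input itself lay below that of the double mutant (-1.48, limma adjusted p = 0.049), which adds to its enrichment. This input call ended when single libraries were left out. The value of the spindle organizer MZT2B (4.22 ± 0.12) is uncertain because of its paralog MZT2A, and that of the antisense gene AD000090.1 (4.56) because strand use is not stated. AL034430.1 was listed at 0 in all 3 double-mutant precipitates and at 108 ± 17.1 in those of the CSD mutant, so no fold is given.

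MALAT1 (ENSG00000251562, lincRNA, chromosome 11, 65497688 to 65506516, plus strand), an abundant nuclear RNA, fell by 3.77 ± 0.13: it went from 1896 ± 243 in input to 353 ± 14.2 in the CSD-mutant precipitate, and from 1423 ± 98.6 to 3651 ± 359 with the double mutant (n = 3 each). The non-coding AC245060.5 (-4.23 ± 0.29), AC026362.1 (-4.20 ± 1.05), AC136944.2 (-3.74) and LINC00342 (-3.67) fell, and so did PRR36 (-3.62) and the chromatin remodelling subunit BICRA (-3.50). Values of FAM106A (-4.38), which has near copies, of the pseudogene SMG1P7 (-3.48) and of the antisense gene AL928654.2 (-3.30) are uncertain. RPL24 rose by 1.56 ± 0.10 (adjusted p = 5.2e-09) and MYCN fell by 0.40 ± 0.05 (adjusted p = 6.1e-06). RPS6KB1 fell by 0.59 ± 0.22 (adjusted p = 0.028), a call that ended without CSD-mutant input 2 (adjusted p = 0.075), double-mutant input 2 (0.057) or 3 (0.056), CSD-mutant IP 3 (0.069) or double-mutant IP 2 (0.062), and in limma without the trend (0.058).

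Large-subunit mRNAs gave 44 rises and 1 fall of 46 (median 1.70, adjusted p = 0.163 with an estimated correlation), and small-subunit mRNAs 31 and 0 of 32 (median 1.80, adjusted p = 0.128 with an estimated correlation), including RPS19 (3.82) and RPS15A (0.60). The falling large-subunit gene was RPL32 (-0.24), whose call ended without double-mutant input 1 (-0.20, adjusted p = 0.054) or CSD-mutant IP 1 (-0.19, 0.051). Mitochondrial ribosomal proteins gave 74 and 1 of 77 (median 1.65, adjusted p = 0.0944 with an estimated correlation), with MRPL23 at 3.44 and MRPL10 at -0.52. Nuclear-encoded oxidative phosphorylation genes gave 67 and 1 of 75 (median 1.28, adjusted p = 0.104 with an estimated correlation), led by the complex I subunits NDUFB10 (4.02) and NDUFB7 (3.81). All 13 mitochondrially encoded genes fell (median -1.05, adjusted p = 0.255 with an estimated correlation), from MT-ND2 (-0.71) to MT-ND5 (-2.70).

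Initiation factors gave 31 rises and 7 falls of 43 (median 0.77, adjusted p = 0.128 with an estimated correlation), with EIF3H (2.62) and EIF3M (2.56) above and EIF5B (-1.58) and EIF4G3 (-1.49) below. Elongation factors gave 11 and 1 of 15 (median 0.67, adjusted p = 0.0944 with an estimated correlation), with EEF1B2 at 2.42 and EEF2K at -0.84. Ribosome biogenesis factors gave 39 and 16 of 72 (median 0.46, adjusted p = 0.182 with an estimated correlation), with NOP53 (2.88) opposite UTP20 (-1.83), and 31 and 26 (median 0.09) under equal totals. The secretory pathway gave 30 and 14 of 51 (median 0.39, adjusted p = 0.255 with an estimated correlation), with SEC11C (3.13) opposite COPB1 (-1.20), but equal totals turned the balance to 19 and 22 (median 0.02) and cyclic loess left a median of 0.14. Adrenergic factors gave 4 and 11 of 19 (median -0.56, adjusted p = 0.182 with an estimated correlation), with GATA3 (-1.51) and EYA1 (-1.27) lowest and HAND1 at 0.81.

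Not passed as groups with the CSD mutant were aminoacyl-tRNA synthetases (12 rises and 6 falls of 22, median 0.37, adjusted p = 0.304; 7 and 9, median 0.00, under equal totals), the S6 kinase and mTOR pathway (8 and 13 of 28, -0.27, 0.363) with AKT1 (1.46) opposite RICTOR (-1.81), and neuronal genes (14 and 22 of 53, -0.33, 0.110) with GAP43 (1.71) opposite SYN1 (-1.76). The let-7 targets (12 and 14 of 37, -0.10, 0.747) held CDC34 (2.15) and HRAS (2.04) beside DICER1 (-1.84), the nuclease of microRNA maturation, and fry gave this list the opposite direction. RNA-binding factors (26 and 18 of 50, 0.24, 0.155) turned to medians of -0.13 and -0.01, and cell cycle genes (24 and 15 of 46, 0.23, 0.304) to -0.13 and -0.07, under equal totals and cyclic loess. Histones (4 and 0 of 9, 0.41, 0.322) and mesenchymal markers (2 and 1 of 14, -0.04, 0.968) did not pass, and the mesenchymal counts turned to 1 and 4 under equal totals and their median to 0.13 under cyclic loess. Adjusted over the list alone, counts differed for adrenergic factors (6 rose), ribosome biogenesis (41 rose), RNA-binding factors (27 rose) and mesenchymal markers (1 rose, 0 fell).

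By limma 9195 of 14474 genes passed with the CSD mutant, 4614 higher and 4581 lower, and 2684 and 2480 of these differed at least 2-fold. Equal totals moved the median of all genes from -0.05 to -0.41 and the split to 3273 higher and 6336 lower. By camera 10 of the 18 lists passed, and 0 with an estimated correlation (5 at an unadjusted p under 0.05).

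With the ZKD mutant, the cell cycle gene CKS2 (ENSG00000123975, protein-coding, chromosome 9, 89311198 to 89316703, plus strand), a regulatory subunit of cyclin-dependent kinases, rose most, by 4.36 ± 0.09. It went from 1255 ± 26.8 in input to 12034 ± 966 in the precipitate, and from 1549 ± 90.9 to 722 ± 11.5 with the double mutant (n = 3 each). Its relative CKS1B (3.51 ± 0.08), the ATP synthase subunit ATP5MD (3.88 ± 0.12), the complex I subunit NDUFC1 (3.53 ± 0.12), the ubiquitin-like UBL5 (3.57 ± 0.12), CAMTA1 (3.70 ± 0.15), CGRRF1 (3.67 ± 0.23), CNIH4 (3.43 ± 0.08), HINT1 (3.41 ± 0.09) and the non-coding AC243919.1 (3.41 ± 0.09) rose as well. The giant muscle gene TTN (-3.84 ± 0.78), MALAT1 (-3.78 ± 0.14) and the non-coding AC026362.1 (-4.11), AC136944.2 (-3.53), AC245060.5 (-3.48) and LINC00342 (-3.35) fell. Values of the antisense gene AL928654.2 (-4.42 ± 0.91), the pseudogenes AC124944.2 (-4.04) and HERC2P3 (-3.36), and FAM106A (-3.57) are uncertain.

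RPL24 rose by 1.05 ± 0.08 (adjusted p = 1.8e-08) and MYCN fell by 0.43 ± 0.06 (adjusted p = 1.2e-05). RPS6KB1 had -0.32 ± 0.13 (adjusted p = 0.047) and did not pass without ZKD-mutant input 1 (adjusted p = 0.098) or 2 (0.078), double-mutant input 2 (0.098) or 3 (0.097), ZKD-mutant IP 3 (0.123), or double-mutant IP 1 (0.073) or 2 (0.108). The call also ended with the replicate block (adjusted p = 0.051) and without a filter on low values (0.082).

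Large-subunit mRNAs gave 43 rises and 0 falls of 46 (median 1.32, adjusted p = 0.216 with an estimated correlation), led by RPL9 (3.33) and RPL5 (2.99). Small-subunit mRNAs gave 32 rises of 32 (median 1.44, adjusted p = 0.209 with an estimated correlation), including RPS27A (2.99), while RPS19 had 0.50 and missed the threshold under equal totals (0.12) and cyclic loess (0.09). Mitochondrial ribosomal proteins gave 73 and 1 of 77 (median 1.38, adjusted p = 0.0968 with an estimated correlation), from MRPL13 (3.24) to MRPS26 (-0.40). Nuclear-encoded oxidative phosphorylation genes gave 74 and 0 of 75 (median 1.75, adjusted p = 0.0968 with an estimated correlation), including NDUFB4 (3.40). The secretory pathway gave 41 and 6 of 51 (median 0.86, adjusted p = 0.0968 with an estimated correlation), with the signal peptidase subunit SPCS2 (2.79) opposite COPA (-1.31).

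Initiation factors gave 31 rises and 7 falls of 43 (median 0.93, adjusted p = 0.262 with an estimated correlation), with EIF3E (2.96) and the cap-binding EIF4E (2.27) opposite EIF5B (-1.74) and EIF4G1 (-1.29). Elongation factors gave 11 and 1 of 15 (median 0.56, adjusted p = 0.270 with an estimated correlation), including EEF1E1 (2.20) and EEF1A1 (1.82). Ribosome biogenesis factors gave 39 and 17 of 72 (median 0.42, adjusted p = 0.506 with an estimated correlation), RNA-binding factors 32 and 11 of 50 (0.45, adjusted p = 0.290 with an estimated correlation) and cell cycle genes 24 and 12 of 46 (0.43, adjusted p = 0.538 with an estimated correlation), where CENPF (-3.05) and CENPE (-2.99) lay opposite CKS2. Equal totals turned these counts to 24 and 28 (median 0.04), 22 and 19 (0.07) and 20 and 21 (0.05). Histones gave 10 and 0 of 11 tested, out of 44 listed (median 1.34, adjusted p = 0.141 with an estimated correlation), including HIST1H2AC (2.12). The libraries were polyA-selected, so these values stand for the 11 tested genes and not for the class. Adrenergic factors gave 2 and 8 of 19 (median -0.23, adjusted p = 0.262 with an estimated correlation), with HAND2 (-1.10) and GATA3 (-1.09) lowest.

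The mitochondrially encoded genes split with the ZKD mutant: 7 rose and 3 fell of 13, and their median of 0.28 (adjusted p = 0.427) turned to -0.10 under equal totals and -0.92 under cyclic loess. MT-CO3 (1.68 ± 0.09) and MT-ATP6 (1.45 ± 0.11) were highest, and MT-ND5 (-1.86 ± 0.10), MT-ND6 (-1.64 ± 0.09) and MT-ND3 (-1.04 ± 0.16, named after its value was seen) were the 3 that fell. The MT-ND6 value is uncertain here too, because strand use is not stated. Aminoacyl-tRNA synthetases (9 and 7 of 22, median 0.17, adjusted p = 0.427) turned to -0.21 under equal totals. The S6 kinase and mTOR pathway (6 and 12 of 28, -0.35, 0.218) held RHEB (2.68) and LARP1 (-1.36), a translation regulator of ribosomal protein mRNAs. Neuronal genes (14 and 24 of 53, -0.28, 0.0801) held GAP43 (2.04) and KIF1A (-1.56), and let-7 targets (9 and 16 of 37, -0.25, 0.427) held RRM2 (1.79) and DICER1 (-1.52). Mesenchymal markers (4 and 3 of 15, 0.45, 0.400) included LUM (3.10). Adjusted over the list alone, counts differed for initiation factors (8 fell), aminoacyl-tRNA synthetases (10 rose), mesenchymal markers (1 fell), let-7 targets (17 fell) and mitochondrially encoded mRNAs (5 fell).

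By limma 9346 of 14713 genes passed with the ZKD mutant, 4629 higher and 4717 lower, and 2677 and 2711 of these differed at least 2-fold. Equal totals moved the median of all genes from -0.06 to -0.43 and the split to 3276 higher and 6539 lower. By camera 12 of the 18 lists passed, and 0 with an estimated correlation (4 at an unadjusted p under 0.05).

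**Figure D2:**
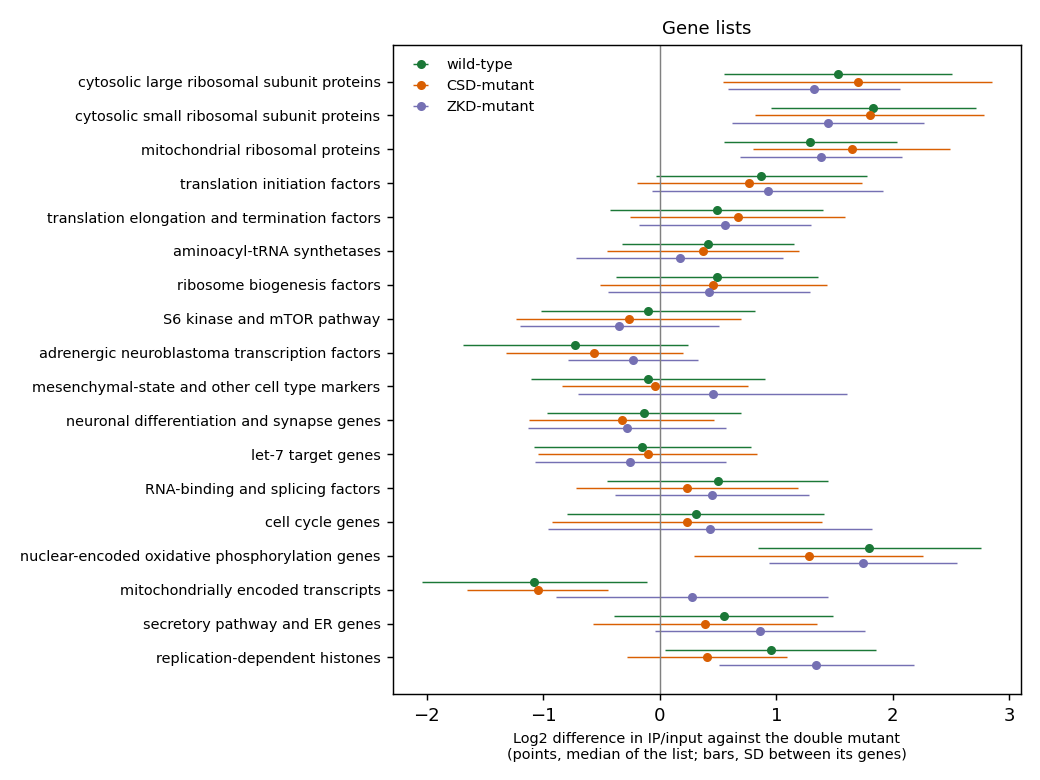
Median log2 difference in IP/input against the double mutant for the 18 lists, with the SD between genes. Scaling turned the direction for mitochondrially encoded mRNAs and aminoacyl-tRNA synthetases with the ZKD mutant, RNA-binding and cell cycle genes with the CSD mutant, and mesenchymal markers with the wild-type form and the CSD mutant.

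The enrichments of the 3 forms overlapped. Of 14329 genes tested in all 3 tables, 2863 rose and 2830 fell with every form, and 310 passed 3 times with mixed directions. Chosen after their values were seen, MYCN, EIF5B, UTP20, GATA3 and PRR36 fell and RPS27A, RPL24, PET100, EIF3H and SEC11A rose with all 3 forms. Correlations were r = 0.824 for the wild-type form and the CSD mutant, 0.832 for the wild-type form and the ZKD mutant, and 0.710 for the 2 single mutants. The same double-mutant libraries entered every comparison, and 20 simulations with no shared effect gave 0.497, 0.510 and 0.506, with covariances of 0.0535, 0.0541 and 0.0545 against the measured 1.08, 1.06 and 0.981. These simulations held only the noise of the shared libraries: the double mutant's own precipitate over input, which is subtracted from every form, had a covariance of 0.530 to 0.531 between tables and enters the measured values too. Without this subtraction, precipitate over input correlated at 0.827, 0.806 and 0.696 between the forms, and at 0.287, 0.329 and 0.196 between the double mutant and the wild-type form, the CSD mutant and the ZKD mutant. Only 3 double-mutant libraries exist per fraction, so the controls could not be divided between forms.

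Differences between forms were set side by side without a test, because each table had been normalized on its own, and the genes given for them were chosen after their values were seen. RPS19 had 3.46 ± 0.07 in precipitate over input with the wild-type form, 4.12 ± 0.04 with the CSD mutant, 0.82 ± 0.06 with the ZKD mutant and 0.31 ± 0.07 with the double mutant of the wild-type table. NOP53, a ribosome biogenesis factor, had an enrichment of 2.88 with the CSD mutant and -0.57 with the ZKD mutant. The let-7 target CDC34 had 2.15 and -0.22, and MRPS26 had 2.65 and -0.40. The complex IV subunit gene NDUFA4 ran the other way, with -0.34 and 1.83. Its CSD call ended without CSD-mutant input 3, double-mutant input 1 or 3, CSD-mutant IP 1 or 3, or double-mutant IP 2 or 3 (adjusted p = 0.056 to 0.115). NOP53, CDC34 and MRPS26 have GC contents of 64.1, 65.9 and 63.4% and NDUFA4 40.4%, and GC content followed enrichment differently by form. Its Spearman correlations were -0.20 with the wild-type form, 0.09 with the CSD mutant and -0.32 with the ZKD mutant, so a GC effect on these differences stays open.

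Precipitate against input gave the levels behind these differences. In the wild-type form, RPS13 (3.86 ± 0.09), RPL18 (3.79 ± 0.07), RPS27A (3.48 ± 0.09) and RPS19 were the highest beside the pseudogene H3F3AP4 (6.31 ± 1.63), whose value is uncertain. AC084018.2 (-3.80 ± 0.21), AC108010.1 (-3.78 ± 0.27), ANKRD10-IT1 (-3.74 ± 0.21), MT-ND3 (-3.64 ± 0.16) and DNM3OS (-3.57 ± 0.23) were the lowest. With the CSD mutant RPS27A (4.16 ± 0.05), RPS19, RPS13 (3.85 ± 0.04) and the DNA repair gene MGMT (3.78 ± 0.11) rose, MGMT from 109 ± 8.45 to 1506 ± 40.2, and AC015813.1 (-4.77 ± 0.38), ANKRD10-IT1 (-4.59 ± 0.24) and AC139256.1 (-4.31 ± 0.26) fell. With the ZKD mutant RPL9 (3.33 ± 0.07), CKS2 (3.26 ± 0.06) and AC243919.1 (3.45 ± 0.06) rose, and the signal recognition particle RNAs RN7SL2 (-5.71 ± 0.33) and RN7SL1 (-5.40 ± 0.28), which have many copies and so uncertain values, fell with MT-ND3 (-4.00 ± 0.12).

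The double mutant still had RNAs above input. IL10RB, a cytokine receptor subunit, rose by 3.57 ± 0.10, and the reductase CYB5R3 (ENSG00000100243, protein-coding, chromosome 22, 42617840 to 42649568, minus strand) by 3.04 ± 0.07, from 1657 ± 98.5 to 13602 ± 571 (n = 3 each). MHENCR (3.02 ± 0.12) and TMEM8B (2.94 ± 0.14) rose, and RN7SL2 (-3.49 ± 0.28), RN7SL1 (-3.28 ± 0.18) and MT-ND3 (-2.97 ± 0.16) fell. Ribosomal and mitochondrial protein mRNAs lay below input, with medians of -0.63 for the large subunit, -0.41 for the small subunit, -0.56 for mitochondrial ribosomal proteins and -0.86 for oxidative phosphorylation. Part of the enrichment of these groups with the other forms is therefore a loss with the double mutant. Adrenergic factors lay above input with the double mutant, with a median of 0.29 (0.06 under equal totals and 0.04 under cyclic loess). With the wild-type form, the CSD mutant and the ZKD mutant it was -0.30, -0.15 and 0.03. As deposited, part of their lower enrichment is therefore a gain with the double mutant.

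By limma, precipitate and input differed for 10216 genes with the wild-type form (5362 higher, 4854 lower), 10721 with the CSD mutant (5531 and 5190), 10355 with the ZKD mutant (5452 and 4903) and 8393 with the double mutant (4449 and 3944), n = 3 per group. Equal totals changed the splits to 3009 and 8105, 3071 and 8296, 2544 and 8627, and 2974 and 5643 (medians of all genes -0.50, -0.57, -0.58 and -0.22), and without a filter they were 5419 and 7515, 5662 and 8371, and 5533 and 7849 for the 3 forms other than the double mutant.

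Transcript length followed the enrichment in protein-coding genes. Spearman correlations with length were -0.46 for the wild-type form, -0.55 for the CSD mutant and -0.46 for the ZKD mutant, and 0.24 for precipitate over input of the double mutant. From the shortest to the longest of 5 length classes the median enrichment was 0.89, 0.37, -0.02, -0.31 and -0.63 with the wild-type form. It was 1.06, 0.48, -0.07, -0.45 and -0.74 with the CSD mutant and 0.89, 0.33, -0.09, -0.40 and -0.71 with the ZKD mutant. The short RPS27A, PET100 and CKS2 and the long TTN, MKI67 and CENPF lay at opposite ends of this trend. Whether the authors' normalization held a length term is not given, so the trend may come from the normalization. Genes are not independent replicates, so no p-value is given.

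**Figure D3:**
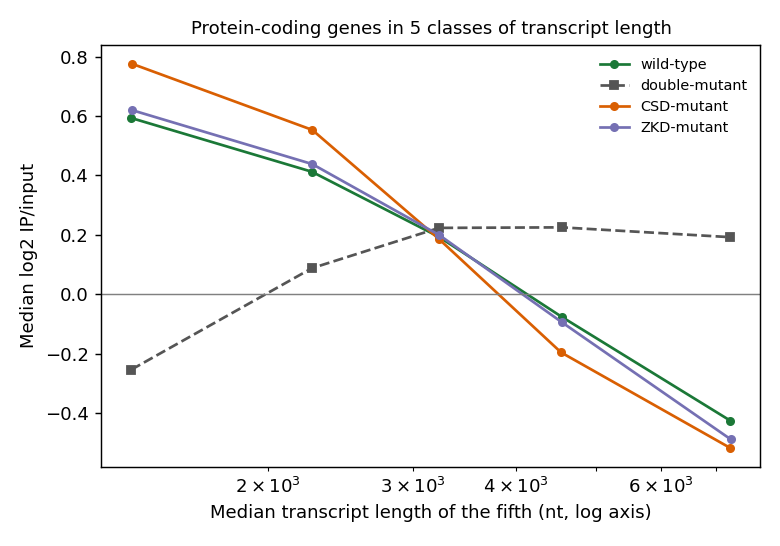
Median log2 IP/input of protein-coding genes in 5 classes of transcript length for each form, with the double mutant from the wild-type table (dashed).

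The inputs differed between forms as well. Against double-mutant inputs, KIRREL1 (ENSG00000183853, protein-coding, chromosome 1, 157993273 to 158100262, plus strand), a cell adhesion gene, rose with the wild-type form by 4.58 ± 0.21 (adjusted p = 3.4e-09), at 224 ± 20.4 against 8.45 ± 1.65. The actin-bundling gene LCP1 (4.38 ± 0.20), the basement membrane collagens COL4A1 (3.55 ± 0.33) and COL4A2 (3.54 ± 0.17) and CRB2 (2.93 ± 0.16) rose, and neuropeptide Y, NPY, fell by 2.46 ± 0.09, from 1663 ± 31.7 to 301 ± 12.7. MAGEA12 (-2.98 ± 0.22), IGHM (-2.27 ± 0.12), S100A10 (-2.20 ± 0.19) and ARHGAP36 (-2.16 ± 0.10) fell as well. SLITRK1, a neuronal membrane protein, fell with the CSD mutant (-2.79 ± 0.27) and the ZKD mutant (-2.66 ± 0.25), as did CAPN6 (-1.68 ± 0.12 and -2.17 ± 0.13), and VSTM4 rose with both (1.34 ± 0.12 and 1.55 ± 0.12). The same double-mutant inputs entered every input comparison, so a difference found with more than 1 form may lie in the double mutant alone. CLMN (1.60 ± 0.29), the monoamine transporter SLC18A2 (1.17 ± 0.09) and KITLG (1.12 ± 0.19) rose and GBP2 (-1.47 ± 0.25) fell with the CSD mutant. CDH4 (1.49 ± 0.16) and STK32A (1.38 ± 0.29) rose and the sensory neuron factor POU4F1 (-1.52 ± 0.23), MAGEA12 (-1.30 ± 0.17) and CDH10 (-1.18 ± 0.19) fell with the ZKD mutant.

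By limma 2910 genes differed between wild-type and double-mutant inputs (1088 higher, 1822 lower), 1108 for the CSD mutant (470 and 638) and 2878 for the ZKD mutant (1301 and 1577), n = 3 per group, and cyclic loess changed the first 2 splits to 1335 and 1374 and to 561 and 482. Single libraries moved these counts: the wild-type count was 1806 without wild-type input 1 and 1773 without double-mutant input 2. For the ZKD mutant it was 1614 without ZKD-mutant input 1 and 1560 without double-mutant input 2, and for the CSD mutant 516, 669 and 637 without CSD-mutant input 1, 2 and 3 and 443 and 672 without double-mutant input 2 and 3.

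The authors' table of comparisons gave close values for the same genes. For LIN28B its log2 values were 0.51, -0.26 and -0.52, for RPL24 0.83, 1.57 and 1.05, and for MYCN -0.74, -0.40 and -0.43 in the order wild-type, CSD mutant and ZKD mutant. For RPS6KB1 it gave -0.09 (adjusted p = 0.727), -0.59 (0.0221) and -0.33 (0.0672), so the ZKD value passed only in part of the settings used here and not there. Correlations with the enrichments computed here were 0.993, 0.993 and 0.995, and 7668, 7834 and 7942 genes passed both ways in one direction with 0 in opposite directions, where each analysis used its own set of genes.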

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

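The tests of whole mitochondria and of mitochondrial RNA in the inputs were chosen only after the result was seen. Of 18 lists and 183 named genes, 1 list and 15 genes are given here because all 3 IP/input ratios of one form lay above all 3 of the double mutant and all 3 of another form lay below them. These differences between forms were not tested, since each table was normalized on its own.

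The list was the mitochondrially encoded mRNAs, with ZKD mutant minus CSD mutant at 1.48 (form less double mutant in the list's median IP/input: -0.71 with the CSD mutant, -0.67 with the wild-type form and 0.77 with the ZKD mutant; the median of the differences per gene was lower with the ZKD mutant, 0.28, and turned to -0.92 under cyclic loess). The differences of the 13 spread with an SD of 1.17, from -1.86 for MT-ND5 to 1.68 for MT-CO3. Their SD was also 0.97 with the wild-type form and 0.60 with the CSD mutant, so this spread cannot count against whole mitochondria carried into the precipitate. All but MT-ND3, 12 of 13 genes, were higher with the ZKD mutant than with either of these forms, and such carry-over stays open. Less mitochondrial RNA in the ZKD-mutant input would raise IP/input, but all 13 were above the double mutant in the inputs (median difference 0.28, SD between genes 0.12), which argues against it. The authors' scaling stays open too, as does a change of binding once the zinc knuckles are mutated.

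Among the mitochondrially encoded genes, ZKD mutant minus CSD mutant was 2.24 for MT-ATP6, 2.09 for MT-ATP8 and 2.45 for MT-CO3, and ZKD mutant minus wild-type form was 1.54 for MT-ND2. MT-ATP6 and MT-ATP8 overlap on the same strand, so their values are not separate results. The wild-type value of MT-CO3, 0.90, turned to -0.11 under cyclic loess. Among mRNAs for cytosolic ribosomal proteins, RPL32 had ZKD mutant minus CSD mutant of 1.71 and RPS26 ZKD mutant minus wild-type form of 1.53. Both have processed pseudogenes, and the CSD-mutant fall of RPL32 ended without double-mutant input 1 (adjusted p = 0.054) or CSD-mutant IP 1 (0.051).

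For mitochondrial ribosomal proteins, MRPL4 had CSD mutant minus wild-type form of 1.22, MRPS2 ZKD mutant minus wild-type form of 1.05, and MRPS26 CSD mutant minus ZKD mutant of 3.05. NDUFA4 had ZKD mutant minus CSD mutant of 2.18, where its CSD-mutant call ended without CSD-mutant input 3, double-mutant input 1 or 3, CSD-mutant IP 1 or 3, or double-mutant IP 2 or 3 (adjusted p = 0.056 to 0.115). EEF2 had CSD mutant minus wild-type form of 0.82, and its wild-type fall ended without wild-type input 2 (adjusted p = 0.056) or double-mutant input 1 (0.053). NOP53 had CSD mutant minus ZKD mutant of 3.45, CDC34 2.37, and SEC61B ZKD mutant minus wild-type form of 1.63. LIN28B had wild-type form minus ZKD mutant of 1.03, and its wild-type value of 0.51 shrank to 0.09 under cyclic loess.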

How the results depend on the processing

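Leaving out double-mutant libraries for the correlations between forms, equal totals for the gene lists and the margin used for matched lists were chosen only after the result was seen. Of the alternatives for the main results 277 were classed as the same, 16 as weaker, 2 as stronger, 11 as moved and 1 as reversed. The cause was not tested. A count of genes or lists was the same if it stayed within 1.5 times of the main count, whatever its split into higher and lower. LIN28B levels were the same if direction and side of the threshold held. Correlations were the same if they moved by no more than the SD of the values with 1 library left out. Requiring a difference of at least log2 0.5 with limma treat lowered the enrichment counts to 5009, 5373 and 5645 (wild-type, CSD and ZKD), which follows from the stricter hypothesis. Leaving out 1 library gave 8436 to 9024, 8729 to 9020 and 8882 to 9288 genes. Input counts were less stable: 1773 (without double-mutant input 2) to 3299 (without wild-type IP 1), 443 (without double-mutant input 2) to 1160 (without double-mutant IP 1), and 1560 (without double-mutant input 2) to 2946 (without ZKD-mutant IP 1). They also fell below the main count by over 1.5 times without wild-type input 1 (1806), ZKD-mutant input 1 (1614), CSD-mutant input 1, 2 or 3 (516, 669, 637) or double-mutant input 3 (CSD table, 672), and without the trend the CSD input count was 599. LIN28B in the CSD-mutant precipitate turned from 0.35 to -0.026 under equal totals, and its ZKD-mutant input difference ranged from 0.13 to 0.20 with 1 library left out, passing only without ZKD-mutant input 1 (adjusted p = 0.045). The calls of RPS6KB1 that ended without 1 library are named in the report; the CSD call also ended without the trend (adjusted p = 0.058) and the ZKD call without a filter (0.082) and with the replicate block (0.051).

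A correlation estimated by camera left 0, 0 and 0 lists (3, 5 and 4 at an unadjusted p under 0.05), and fry called 17, 17 and 16. With the replicate block the lists called were 13, 10 and 12, the enrichment counts 8801, 9033 and 9223, the IP against input counts 10124, 8257, 10659 and 10250 (wild-type, double-mutant, CSD, ZKD) and the input counts 2928, 1030 and 2829. Correlations between forms were 0.823 (wild-type and CSD), 0.831 (wild-type and ZKD) and 0.711 over the genes tested in both tables of a pair. They were 0.835 and 0.840 for the first 2 with a pseudocount of 5 and 0.848 and 0.849 at a mean of at least 50, and ran from 0.821 to 0.828, 0.828 to 0.835 and 0.707 to 0.719 with 1 double-mutant library left out. For each of the 10 counts of genes the real split was the only 1 of 10 splits with as many; the highest other count was 1 for wild-type and ZKD enrichment (8897 and 9346) and CSD IP against input (10721), and 0 for CSD enrichment (9195), IP against input of the other forms (10216, 8393, 10355) and inputs (2910, 1108, 2878). A set of 10 splits is too few for a share under 0.05.

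Among genes and lists 7815 values stayed the same, 220 were weaker, 69 stronger and 39 reversed, and the cause was not tested. Reversed under equal totals were RPL28 (-0.24), RPL32 (-0.21) and RPS15A (-0.047) with the wild-type form, MRPS30 (-0.32) with the CSD mutant, and RPL13 (-0.33) and NDUFV1 (-0.090) with the ZKD mutant. Under cyclic loess these were RPL28 (-0.31), RPL32 (-0.19), RPS15A (-0.11) and MT-CO3 (-0.11) with the wild-type form, MRPS30 (-0.020) and HIST1H2BK (0.00052) with the CSD mutant, and RPL13 (-0.33) and the mitochondrially encoded list (-0.92) with the ZKD mutant. In precipitates alone they were RPL28 (-0.035) and RPL32 (-0.015) with the wild-type form, LIN28B (0.35), DCN (-0.62) and HIST1H2BK (0.17) with the CSD mutant, and RPL28 (0.048) and RPL13 (-0.064) with the ZKD mutant; fry reversed the let-7 list of the CSD mutant (-0.10). Without 1 library these values, none past the threshold, ran over both signs: with the CSD mutant MRPS30 -0.055 to 0.12 (turned by CSD-mutant input 1 or IP 2, or double-mutant IP 1), HIST1H2BK -0.24 to 0.13 (CSD-mutant input 1 or 2 or IP 2, double-mutant input 1 or IP 1 or 3), RPL26 -0.063 to 0.035 (CSD-mutant input 2 or IP 1 or 2, double-mutant input 3 or IP 2) and RPS26 -0.11 to 0.021 (double-mutant IP 1 or 2), and with the ZKD mutant RPL13 -0.0060 to 0.094 (ZKD-mutant input 1).

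Calls that ended without 1 library also included RPS15A (wild-type; wild-type input 1 or IP 2 or 3, double-mutant input 2 or IP 3, adjusted p up to 0.087), COL1A1 (wild-type, 0.052 to 0.069; CSD, 0.051 to 0.084), LMO1 (0.050 to 0.105) and FN1 (0.057 to 0.104) with the ZKD mutant, and the named H3F3AP4 of the double-mutant precipitate (at least 0.096), SMIM11B (up to 0.152) and AC099329.1 (up to 0.205) of the ZKD-mutant precipitate. In the inputs these were GLI2 (up to 0.153), STUM (up to 0.184) and AL139300.1 (up to 0.110) with the CSD mutant and AC124944.2 (up to 0.177) and LINC01002 (up to 0.090) with the ZKD mutant. Count tests on whole reads and the test of the wild-type form against each single mutant were not run, because the values hold no whole reads and the tables were normalized separately. Raw depth is unknown, so how far it limits genes with low values could not be measured.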

Other observations

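The test of long non-coding RNA in the inputs, the gene families chosen by name, the margin used for matched lists and the fit that moved matched genes were chosen only after the result was seen. The length test of long non-coding RNA was written down before its result was seen. The families had no set test, so counts and medians are given without a p-value. Of all tested genes 4579 of 14757 rose with the wild-type form, 4614 of 14474 with the CSD mutant and 4629 of 14713 with the ZKD mutant. Proteasome subunits gave 44 rises and 1 fall of 46 with the wild-type form (median 1.64), 43 and 1 with the CSD mutant (1.38) and 41 and 1 with the ZKD mutant (1.37). Sm and LSm proteins of the spliceosome gave 18 and 1, 20 and 1, and 19 and 2 of 21 (medians 1.78, 1.68 and 1.15). Chaperonin subunits gave 9 rises of 9 with the wild-type form, 8 of 8 with the CSD mutant and 8 of 8 with the ZKD mutant (1.55, 1.21 and 1.18), and import subunits of the TIM and TOM complexes 22, 21 and 22 rises and 0 falls of 24.

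Falls were 4318, 4581 and 4717 among all tested genes. Kinesins gave 2 rises and 23 falls, 4 and 23, and 1 and 21 of 32 (medians -0.98, -0.86 and -0.89), and protocadherins 27, 32 and 26 falls of 54, 50 and 51 (medians -0.85, -0.95 and -0.78). Zinc finger genes of the ZNF series gave 62 rises and 124 falls of 450, 66 and 134 of 445, and 41 and 156 of 447, so most passed in neither direction (medians -0.15, -0.28 and -0.32). The medians of these families kept their sign under equal totals and cyclic loess. In the wild-type comparison their median annotated lengths were 1566 nt for proteasome, 1763 for Sm and LSm, 2150 for chaperonin and 1694.5 for import genes. They were 5496.5 for kinesins, 4776.5 for protocadherins and 3548.5 for ZNF genes. The shortest and longest length classes had median enrichments of 0.89 and -0.63. Families were not matched for length, so how much of their shifts follows length was not tested.

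Cytosolic ribosomal protein mRNAs had median enrichments over both subunits of 1.71, 1.75 and 1.38. Neither subunit passed with any form with an estimated correlation (large subunit adjusted p = 0.207, 0.163 and 0.216, small subunit 0.199, 0.128 and 0.209). Matching on annotated length alone left a gap of at least 0.25: the highest 2.5% of lists matched for length began at 1.11, 1.26 and 1.13. Length was taken from 1 transcript per gene, which was long for some members (RPL28 4796 and RPL13 4498 nt, list median 994.5 nt). Enrichment was higher for shorter genes, so if the mRNAs present are shorter than annotated, this bar is too low and length stays open. Reads shared with pseudogenes were argued against as the whole cause, since the 26 genes with the fewest processed pseudogenes, of 78, still had medians of 1.69, 1.77 and 1.10. These had up to 4 such pseudogenes each, and the 7 with at most 1 had medians of 2.14, 2.14 and 1.07. The only 1 with none had 0.06, 0.98 and -0.14, and passed as a rise with the CSD mutant alone. The other 52 had 1.71, 1.75 and 1.60, so a part stays open, most of all with the ZKD mutant. For length, GC content and abundance together the medians lay above the highest 2.5% of matched lists, which began at 1.43, 1.37 and 1.38 (SD of the matched medians 0.137, 0.168 and 0.101; gap with the ZKD mutant 0.00015). Matched genes were still longer and less abundant. Once a fit had moved them to the same properties, the gap was 0.017 with the wild-type form (SD 0.130), 0.167 with the CSD mutant (SD 0.154) and -0.376 with the ZKD mutant (SD 0.109). As annotated, these properties together therefore fit the ZKD-mutant value and cannot be told apart from an effect of LIN28B with the wild-type form or the CSD mutant. The CSD-mutant gap lay just beyond the SD of the matched medians, but it cannot decide. Matched genes were drawn one by one, so their spread leaves out the correlation between members. With the CSD mutant this was estimated at 0.588 for the large and 0.512 for the small subunit. The limit on annotated length holds here too. Binding of this class of mRNA was not tested, and whether the authors' normalization held a length term is unknown.

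Long non-coding RNAs had median enrichments of -0.30, -0.41 and -0.32. They gave 199 rises and 343 falls of 1457 with the wild-type form, 198 and 404 of 1352 with the CSD mutant, and 196 and 394 of 1454 with the ZKD mutant. Rises and falls both took a smaller share than among all tested genes (falls 4318 of 14757, 4581 of 14474 and 4717 of 14713). They lay below input with the double mutant too (median -0.55 in each table, against -0.88, -0.92 and -0.89 with the other forms). Protein-coding lists matched for length and abundance had 2.5th percentiles of 0.07, 0.17 and 0.06, a gap of at least 0.37, which argues against transcript length as annotated. Length again came from 1 transcript per gene. If these RNAs are longer than annotated, the matched lists lie too high, so actual length stays open. GC content was not matched in this test and stays open too. Inputs had more of these RNAs than double-mutant inputs (median differences 0.14, 0.17 and 0.24), which lowers IP/input. In precipitates alone the medians were -0.15, -0.28 and -0.07 against -0.02, -0.05 and -0.03 for all genes, a gap of at least 0.038, so the inputs as a cause stay open. Cyclic loess shrank the medians to -0.10, -0.20 and -0.07 against -0.04, -0.05 and -0.04 for all genes, so a scaling that depends on level stays open. A place in the nucleus, away from LIN28B, may be another cause and was not tested.

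Binding of the zinc knuckles to GGAG was a hypothesis written before the data were examined: GGAG was to rank among the 13 tetramers with the highest partial correlation with enrichment in the forms with intact zinc knuckles. It was not borne out, with rank 97 of all tetramers for the wild-type form (partial rho 0.03) and 79 for the CSD mutant (0.03), against 216 for the ZKD mutant (-0.03). The test used whole transcripts and not binding sites.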
